A study of Homo sapiens with 12 samples.

How the data were processed

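Poly(A)-selected RNA of U251 cells was sequenced with a stranded messenger RNA kit on a NovaSeq instrument in 12 samples, 3 in each of 4 groups: shCTRL and shINCA1 cells, each untreated or treated with IFNγ for 24 h. The deposited table holds expected_counts, that is, estimated counts per gene symbol that are whole numbers and are not scaled between samples. Per the submitters' processing notes, FastQC, Trimmomatic, HISAT2, StringTie and the human genome build hg19 were used. Versions, the order of the steps, the annotation, the counting step and its strand setting are not given in the sources used here. Low values pile up at 3 (5790 times), 6 (4120), 9 (2388) and 12 (1458), against 2186 times at 2 and 1317 at 4. In many cases 1 sequenced fragment therefore appears to be worth about 3 units, though the value 1 (3681 times) does not follow this. Counting intervals computed on these units are therefore too narrow, and a floor of 3 counts stands for about 1 fragment. Intervals and floors cover counting error only.

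Samples were grouped by the titles and the treatment labels, and every column of the table was mapped. Library totals were 46525032 to 66242859 estimated counts. The floor, 3 counts in each library of a group over the scaled total of its libraries, was 0.0552 CPM in untreated shCTRL, 0.0523 in IFNγ shCTRL, 0.0487 in untreated shINCA1 and 0.0561 in IFNγ shINCA1 cells. A fold against a group at 0 in all libraries was computed against this floor and is given as a lower bound. Where a group held 9 counts or fewer without being at 0, the ratio is given with a 95% exact interval of the pooled counts, and no fold is given for differences of responses of such genes. Of 27685 genes 7434 were at 0 in all libraries, and the 4 entries of 2 duplicated symbols were treated as separate genes.

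Counts were fitted in R 4.3.3 with edgeR 4.0.16: the filterByExpr filter on the 4 groups (15769 genes with 99.986% of the counts), TMM factors, and quasi-likelihood tests (glmQLFit, glmQLFTest) with all 12 samples in 1 fit and 1 coefficient per group. The common biological coefficient of variation was 10.6%. Tests were two-sided, with Benjamini-Hochberg adjustment over the tested genes of a comparison and a threshold of 0.05. The comparisons were the IFNγ response in each line, shINCA1 minus shCTRL without and with IFNγ, the difference of the IFNγ responses, and the average IFNγ response, whose genes at a log2 change of at least 1 were followed in the difference. Standard errors are the log2 fold change divided by the square root of the F statistic. The count of genes whose libraries did not overlap is given beside 10%, the share chance gives for 3 against 3. Gene symbols were joined to a GRCh38 annotation for chromosome and order alone, since the counts were made on hg19, and no coordinates are given.

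Gene lists were tested with camera of limma 3.58.1 at a correlation of 0.01, with Benjamini-Hochberg adjustment over 105 tests (21 lists in 5 comparisons). Camera called 55 of them, and 33 of these calls held with a correlation estimated from the data. The lists, fixed before the data were examined, were antiviral interferon-stimulated genes, JAK-STAT signalling, MHC class I and class II presentation, guanylate-binding proteins, chemokines and cytokines, checkpoint and suppression genes, cell death, NF-κB and inflammation, proliferation, the chromosome 9 genes around CD274, the HNRNP H and F family, mesenchymal and matrix genes, neural, glial and stem genes, hypoxia and glycolysis, the unfolded protein and stress response, p53 targets, cholesterol synthesis, replication histones, immune cell markers, and endothelial and epithelial markers. A list of mitochondrially encoded genes was not tested, as 0 of its 15 genes are in the table.

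The genes named were chosen by a rule written before the data were examined. It names CD274, JAK2, IDO1, IRF1, PDCD1LG2, HNRNPH1 and the table's INCA1 in every comparison. It adds the 8 raised and the 8 lowered genes with the largest log2 change among those past the threshold, with an average of at least 1 CPM and libraries that did not overlap (no overlap condition for the difference of responses), and up to 4 members of a list by p. In 1 deviation from it, Y-linked genes are left undescribed, among them DAZ1, which the rule names in the comparison of lines with IFNγ. Some further genes that the rule names are not reported here. Genes listed at 0 in 1 line were chosen after their values were seen.

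The alternatives planned before the data were examined were DESeq2 size factors and upper-quartile factors, no filter and a filter of 5 CPM in 3 samples, the DESeq2 1.42.0 Wald test, limma-voom, the replicate number as a block, only the 2 groups compared, each library left out in turn, an adjusted p of 0.01, a minimum fold of 2 (glmTreat), an estimated correlation, and fry. Alternatives planned for FPKM values were not run, since the table holds counts. Subtracting the median of neighbouring genes, leaving out chromosomes 6 and 14, and leaving out genes near the floor were added after seeing the data. Replicate numbers did not pair the samples: correlations of residuals were -0.0358 to 0.0671 for libraries of the same number and -0.0697 to 0.0506 for others, and 1 of 12 libraries had its best match at its own number in all 3 other groups.

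The fit was tested on simulated data with 3 samples in each of 4 groups. Changes were put into the IFNγ shCTRL group alone, in genes of at least 1 CPM, and all groups otherwise had the same levels. The simulation therefore does not cover a broad difference between the lines. In the IFNγ response 71.6%, 92.5% and 98.5% of genes changed 1.5-fold, 2-fold and 4-fold were called, and 46.3%, 88.1% and 97% in the difference of responses, with at most 8 false calls in any comparison of 15769 simulated genes. A set of 20 changed genes had a camera p of 1.48e-285 and a set of 20 unchanged genes 0.744, and all of 25 shifted windows of neighbouring genes were found without a false one among 475. The windows were shifted by -0.6 in shuffled values, well past the limit of 0.4, so finding them says little about smaller shifts. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for windows and plots.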

Results

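Poly(A) RNA was sequenced from U251 cells, an established human glioblastoma line, that stably carried either a control short hairpin RNA (shCTRL) or a hairpin against the long noncoding RNA called INCA1 in the study (shINCA1). Cells of each line were left untreated or were treated for 24 h with interferon gamma (IFNγ), a cytokine that signals through the kinases JAK1 and JAK2. The series addresses whether this RNA, made from the locus of the checkpoint ligand genes CD274 and PDCD1LG2, takes part in the interferon response of tumour cells. The 12 libraries formed 4 groups of 3, with 46525032 to 66242859 estimated counts per library and 16724 to 17216 genes above 0. Of 27685 genes in the table, 15769 were tested. Nothing in the labels says that the 3 samples of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical. Replicates had correlations of log CPM (counts scaled to a common library size) of 0.983 to 0.987. The first principal component held 57% of the variance and placed every shCTRL library between -73.05 and -54.95 and every shINCA1 library between 57.1 and 69.9. The second held 15.9% and separated treated from untreated libraries in both lines.

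The targeted RNA could not be followed under its own name. The reference annotation lists the noncoding RNA of the CD274 locus as INCR1, and its level was not analysed here. The table's INCA1 entry is a protein-coding gene of chromosome 17 with 5 to 19 counts per library, and it did not pass the test in any comparison. Its log2 difference between shINCA1 and shCTRL was -0.89 ± 0.57 (SE) without IFNγ (adjusted p = 0.204) and 0.50 ± 0.57 with IFNγ (adjusted p = 0.479). Its IFNγ response was -0.70 ± 0.56 in shCTRL (adjusted p = 0.482) and 0.69 ± 0.57 in shINCA1 (adjusted p = 0.610), and these responses differed by 1.39 ± 0.80 (adjusted p = 0.582). The hairpin labels were therefore not checked against the level of their target. Each hairpin was represented by 1 line as far as the labels tell, so a difference between shINCA1 and shCTRL is also a difference between lines.

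The response of control-hairpin cells to IFNγ was asked first. In shCTRL cells the chemokine gene CXCL9 was at 0 counts in every untreated library and at 127 ± 4.62 CPM (SD, n = 3) after IFNγ, at least 2288-fold higher. GBP4, a guanylate-binding protein gene, rose at least 2057-fold, IDO1, a tryptophan-degrading enzyme, at least 1820-fold, CIITA, the transactivator of MHC class II genes, at least 678-fold, and the chemokine CXCL11 at least 610-fold, all from 0 in untreated cells. CXCL10 rose by a ratio of 9117 (95% exact interval 3119 to 44213), and the pseudogene-like LGALS17A and GBP1P1, whose reads may belong to related genes, rose at least 278-fold and 186-fold. CD274, which encodes PD-L1, rose from 6.69 ± 0.41 to 95.2 ± 3.12 CPM, a log2 change of 3.83 ± 0.12 (SE, adjusted p = 2.94e-10). The transcription factor gene IRF1 rose by 5.96 ± 0.06, the kinase gene JAK2 by 1.94 ± 0.08 and PDCD1LG2, which encodes PD-L2, by 3.46 ± 0.17, each with an adjusted p of at most 3.36e-08. CD274 and PDCD1LG2 overlap the noncoding RNA, and the strand setting of the counting is not given in the sources used here, so their counts may include its reads. The RNA-binding protein gene HNRNPH1 did not pass the test (-0.04 ± 0.02, adjusted p = 0.155).

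Fewer genes fell by a large amount in shCTRL cells. The chemokine receptor gene CXCR4 changed by -2.45 ± 0.28 on the log2 scale, HAS2, a hyaluronan synthase, by -1.91 ± 0.18, and FILIP1L by -1.83 ± 0.15. SOSTDC1, CEMIP and NTF3 changed by -1.78 ± 0.36, -1.67 ± 0.26 and -1.64 ± 0.28. GPC3 was lower by a ratio of 9.5 (95% exact interval 2.92 to 48.9), from 0.172 CPM, and its call was lost without shCTRL IFNγ library 3 (adjusted p = 0.053). BOLA2, which has a duplicate copy that could take its reads, fell by 3.24 ± 1.01 (adjusted p = 0.0479), a call lost without any 1 of the 6 IFNγ libraries or without untreated shCTRL library 1 or 2 (adjusted p 0.0632 to 0.135).

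Interferon-related gene lists rose as groups in shCTRL cells. Of 36 antiviral interferon-stimulated genes, 34 rose, also when adjusted over the list alone (camera adjusted p = 2.54e-78). Examples are DTX3L (3.03 ± 0.04), IFIT5 (1.81 ± 0.03), IFIT2 (3.90 ± 0.07) and IFIH1 (3.59 ± 0.07). Of 21 MHC class I presentation genes, 19 rose and 19 adjusted over the list alone (adjusted p = 9.57e-55), led by the peptide transporter gene TAP1 (5.45 ± 0.04), with HLA-E (2.94 ± 0.04), PSMB8 (2.71 ± 0.04) and NLRC5 (4.44 ± 0.09). HLA genes share reads with each other, so their single values are uncertain. Of 14 MHC class II genes, 12 rose, and 13 adjusted over the list alone (adjusted p = 1.67e-16), among them IFI30 (2.34 ± 0.04), CTSS (4.26 ± 0.27) and CD74, which was at least 68.1-fold higher. All 7 guanylate-binding protein genes rose, and 7 adjusted over the list alone (adjusted p = 9.14e-33). GBP5 was at 6.25 ± 0.04, GBP2 at 5.12 ± 0.04 and GBP3 at 4.82 ± 0.06.

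The JAK-STAT list had 14 of 18 members raised, and 14 adjusted over the list alone (adjusted p = 1.17e-28), including NMI (2.47 ± 0.05) and IRF9 (2.57 ± 0.10). Of 17 immune checkpoint and suppression genes, 11 rose and 11 adjusted over the list alone (adjusted p = 5.30e-19), WARS, a tryptophanyl-tRNA synthetase, by 3.73 ± 0.02. Chemokine and cytokine genes had 10 of 15 members raised and 1 lowered, and 10 and 3 adjusted over the list alone (adjusted p = 4.42e-17). CSF1 was at 3.37 ± 0.08 and IL15 at 3.78 ± 0.20. Cell death genes had 17 of 23 raised and 1 lowered, and 19 and 1 adjusted over the list alone (adjusted p = 8.03e-33). The apolipoprotein L genes APOL6 (5.79 ± 0.06), APOL2 (3.87 ± 0.05) and APOL1 (7.60 ± 0.10) were among them. NF-κB and inflammation genes had 7 of 19 raised and 2 lowered, and 8 and 2 adjusted over the list alone (adjusted p = 0.0107, and 0.140 with an estimated correlation). VCAM1 was at 3.95 ± 0.21, C3 at 1.47 ± 0.11 and LIF at -0.48 ± 0.06. Genes around CD274 on chromosome 9 had 4 of 17 raised, and 4 adjusted over the list alone (adjusted p = 0.00477, and 0.125 with an estimated correlation), among them CD274, PDCD1LG2 and JAK2.

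Neural, glial and stem genes moved the other way in shCTRL cells, with 5 of 19 lowered and 1 raised, and 6 and 2 adjusted over the list alone (adjusted p = 3.69e-04). SOX4 changed by -0.82 ± 0.04, SOX9 by -0.71 ± 0.04, CD24 by -0.62 ± 0.06 and HES1 by -0.28 ± 0.05. The other 10 tested lists were not past the threshold. Mesenchymal and matrix genes were among them, with 5 of 29 lowered and 3 raised, and 7 and 5 adjusted over the list alone (adjusted p = 0.366), although single members passed. THBS1 changed by -0.76 ± 0.02, ANKRD1 by -0.83 ± 0.03 and CTGF by -0.63 ± 0.04, while the matrix gene TNC rose by 0.45 ± 0.03. None of the 15 replication histone genes passed (adjusted p = 0.299), and 1 of 28 proliferation genes was lowered, 0 adjusted over the list alone (adjusted p = 0.564). Median, mean and test differed in sign for the mesenchymal, HNRNP H and F and endothelial and epithelial lists, none of them called.

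In edgeR's quasi-likelihood test, 1532 genes were raised and 1184 lowered by IFNγ in shCTRL cells at an adjusted p of 0.05, 352 and 78 of them at least 2-fold. The libraries did not overlap for 33.4% of genes, against 10% by chance. With upper-quartile factors the split turned to 1201 raised and 1970 lowered, so the balance between small rises and small falls depended on the scaling.

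**Figure D1:**
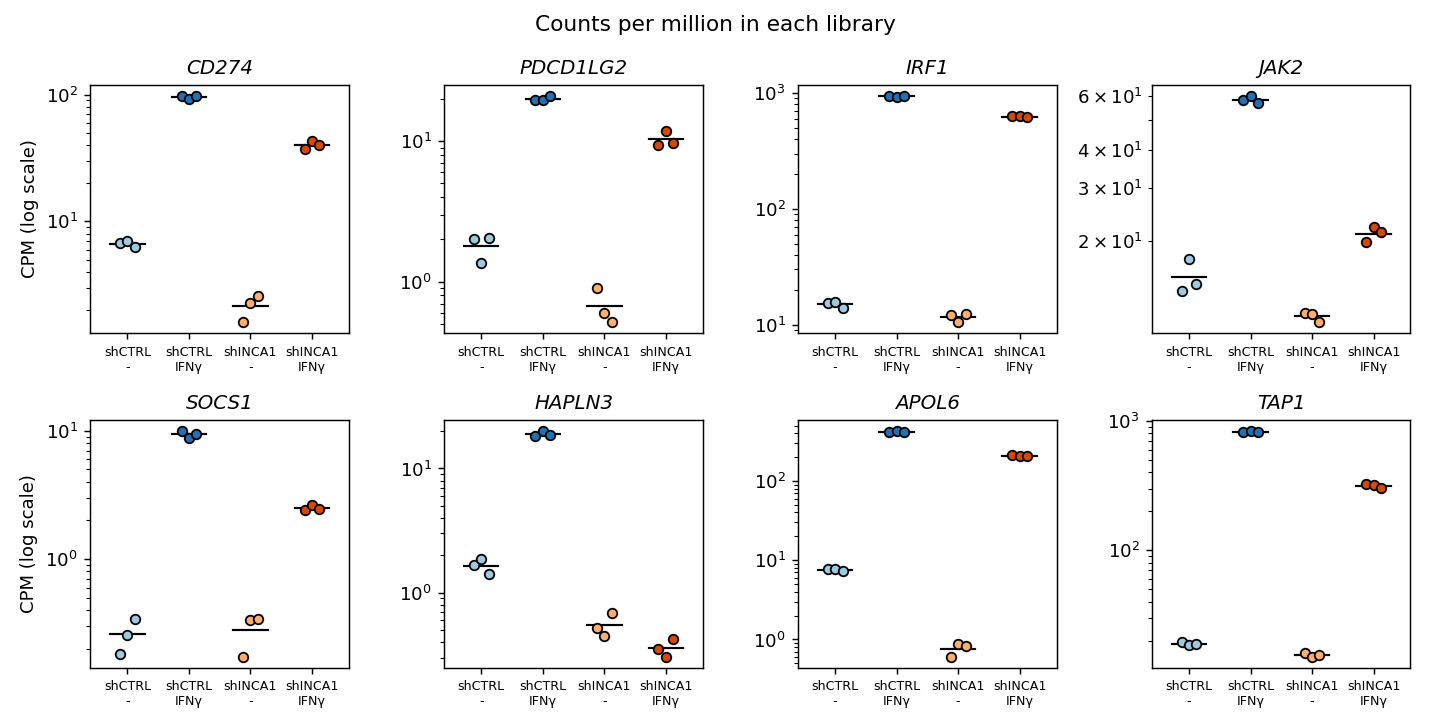
Levels in CPM (log scale) of 8 genes in each of the 12 libraries, where points are libraries, lines are group means of 3, and a dash under a group name means no IFNγ. CD274 rose from means of 6.69 to 95.2 CPM in shCTRL and from 2.16 to 40.1 CPM in shINCA1 cells, while HAPLN3 rose from 1.64 to 19.0 CPM in shCTRL cells and stood at 0.551 and 0.360 CPM in shINCA1 cells.

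The same treatment was then read in cells with the hairpin against INCA1. IDO1 rose at least 447-fold, GBP4 at least 415-fold and CIITA at least 348-fold from 0 counts in untreated shINCA1 cells. GBP1 rose by a ratio of 8902 (95% exact interval 3046 to 43169), RARRES3 at least 103-fold, APOL1 at least 94.9-fold, CXCL10 at least 86.1-fold and the pseudogene-like GBP1P1 at least 47.5-fold. CD274 rose by 4.20 ± 0.13 (SE) on the log2 scale, from 2.16 ± 0.50 to 40.1 ± 2.95 CPM (SD, n = 3). IRF1 rose by 5.75 ± 0.06, JAK2 by 0.90 ± 0.08 and PDCD1LG2 by 3.95 ± 0.19, each with an adjusted p of at most 1.11e-05. HNRNPH1 did not pass the test (0.00 ± 0.02, adjusted p = 0.954).

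Among the genes that fell in shINCA1 cells, CNR1, a cannabinoid receptor gene, changed by -1.54 ± 0.21, NDP by -1.33 ± 0.15, VWF by -1.25 ± 0.23, SOSTDC1 by -1.24 ± 0.25 and GPR55 by -1.10 ± 0.16. CORO7-PAM16, a read-through transcript whose counts can be shared with its parts, went from 2.19 CPM to 0 in every IFNγ library, at least 39.4-fold lower. HIGD1A changed by -1.39 ± 0.39 (adjusted p = 0.0457) and FLG by -1.07 ± 0.29 (adjusted p = 0.0415). Both calls were lost without any 1 of the 6 shINCA1 libraries, HIGD1A also without untreated shCTRL library 1 or 3 or IFNγ shCTRL library 2 or 3 (adjusted p 0.0515 to 0.143), and FLG also without untreated shCTRL library 2 or 3 (adjusted p 0.0518 to 0.150).

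The interferon-related lists rose again. Antiviral genes had 33 of 36 raised, and 35 adjusted over the list alone (camera adjusted p = 3.22e-95). DTX3L was at 3.82 ± 0.05, PARP9 at 4.14 ± 0.08, IFIT2 at 3.64 ± 0.07 and IFIH1 at 3.14 ± 0.07. MHC class I genes had 18 of 21 raised and 18 adjusted over the list alone (adjusted p = 8.35e-66). TAP1 was at 4.35 ± 0.04, NLRC5 at 5.41 ± 0.10, ERAP2 at 3.17 ± 0.06 and HLA-E at 2.37 ± 0.04. MHC class II genes had 7 of 14 raised and 7 adjusted over the list alone (adjusted p = 8.02e-14), IFI30 by 1.21 ± 0.04, and CD74 and CTSS were at least 21.9-fold and 7.30-fold higher. All 7 guanylate-binding protein genes rose, and 7 adjusted over the list alone (adjusted p = 4.91e-44). GBP5 was at 6.21 ± 0.04, GBP2 at 5.67 ± 0.04 and GBP3 at 4.63 ± 0.06.

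Of the JAK-STAT genes 11 of 18 rose, and 11 adjusted over the list alone (adjusted p = 1.32e-28). NMI was at 2.92 ± 0.05 and IRF9 at 3.10 ± 0.11. Checkpoint genes had 11 of 17 raised and 11 adjusted over the list alone (adjusted p = 9.01e-26), WARS by 2.87 ± 0.02. Chemokine and cytokine genes had 10 of 15 raised and 10 adjusted over the list alone (adjusted p = 3.08e-17). CSF1 was at 3.77 ± 0.08, IL15 at 3.25 ± 0.20 and IL7 at 2.27 ± 0.19. Cell death genes had 17 of 23 raised, and 18 raised and 1 lowered adjusted over the list alone (adjusted p = 4.75e-39). APOL6 was at 8.07 ± 0.08 and APOL2 at 3.17 ± 0.05. The chromosome 9 genes around CD274 had 4 of 17 raised, and 4 adjusted over the list alone (adjusted p = 0.00346, and 0.109 with an estimated correlation). Neural, glial and stem genes had 6 of 19 lowered and 2 raised, and the same numbers adjusted over the list alone (adjusted p = 0.0150, and 0.0544 with an estimated correlation). SOX9 was at -0.50 ± 0.04, SOX4 at -0.40 ± 0.04, HES1 at -0.43 ± 0.05 and SOX2 at 0.32 ± 0.04.

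A pair of list calls in shINCA1 cells rested on single libraries. Hypoxia and glycolysis genes had 4 of 22 lowered and 1 raised, and 4 and 1 adjusted over the list alone (adjusted p = 0.0409, and 0.477 with an estimated correlation). This call was lost without IFNγ library 2 or 3 or untreated library 2 or 3 of shINCA1 (adjusted p 0.0529 to 0.195). Targets of p53 had 2 of 14 lowered and 2 adjusted over the list alone (adjusted p = 0.0305, and 0.187 with an estimated correlation), and 0.20 without shINCA1 IFNγ library 2. The unfolded protein and stress list was not called, with 4 of 20 lowered and 1 raised, and 5 and 1 adjusted over the list alone (adjusted p = 0.0724), and passed without untreated shINCA1 library 1 (0.0118). Median, mean and test differed in sign for the mesenchymal, replication histone, immune cell and endothelial and epithelial lists, none of them called.

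IFNγ raised 967 and lowered 465 genes in shINCA1 cells in edgeR's quasi-likelihood test, 237 and 23 of them at least 2-fold, and 24.9% of genes did not overlap, against 10% by chance. With upper-quartile factors 815 were raised and 733 lowered, DESeq2 called 971 and 733, and without untreated shINCA1 library 3 the lowered genes numbered 281.

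Both lines shared many of the called genes. The raised lists had 825 genes in common where independent lists of their sizes would share 93.95, and the lowered lists had 342 in common where 34.9 would be shared. The groups compared have no library in common, but both comparisons come from 1 fit with a shared estimate of the spread. The calls of the lines are therefore not fully independent. Across 14993 genes above the floor in all groups, the responses of the lines had a Pearson r of 0.615, a Spearman rho of 0.434 and a slope of 0.536 of shINCA1 on shCTRL, and genes are not independent replicates. Over 229 genes raised in the average response, r was 0.822 and the slope 0.924.

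The lines with the hairpin against INCA1 and with the control hairpin were compared next, without IFNγ. COL17A1, a collagen of epithelial adhesion, was at 4.59 CPM in shCTRL and 382 CPM in shINCA1 cells, a log2 difference of 6.38 ± 0.05 (SE). PDE3B (6.05 ± 0.47), COL11A1 (5.16 ± 0.20), RIMS1 (5.14 ± 0.46) and the chemokine CXCL14 (5.11 ± 0.16) were higher too, and GJB5 and CDH23 were higher by ratios of 308 (95% exact interval 105 to 1495) and 84.6 (38.7 to 232). COL1A2, a chain of collagen I, stood at 41.5 CPM in shCTRL cells and at 0 in every shINCA1 library, at least 854-fold lower. HAPLN1, a hyaluronan link protein gene, was at least 419-fold lower, PDZRN3 at least 282-fold, PTGFR at least 211-fold, ZNF518B and PICK1 at least 167-fold, HSD17B7, which has a pseudogene copy, at least 140-fold and TLL1 at least 136-fold.

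Genes of the interferon pathway were lower in shINCA1 cells before any IFNγ was added. CD274 differed by -1.62 ± 0.13 (adjusted p = 4.35e-07), PDCD1LG2 by -1.44 ± 0.21 (adjusted p = 8.78e-05), JAK2 by -0.42 ± 0.08 (adjusted p = 7.98e-04) and IRF1 by -0.36 ± 0.05 (adjusted p = 1.04e-04). HNRNPH1 differed by -0.12 ± 0.02 (adjusted p = 1.48e-04), and IDO1 was at 0 in both lines. Antiviral genes had 19 of 36 lowered and 4 raised, and 19 and 4 adjusted over the list alone (camera adjusted p = 3.07e-04). DTX3L (-1.39 ± 0.04), PARP9 (-1.69 ± 0.07), IFIT1 (-2.42 ± 0.11) and IFITM1 (-3.55 ± 0.17) were among them. JAK-STAT genes had 11 of 18 lowered and 2 raised, and 11 and 2 adjusted over the list alone (adjusted p = 0.00572, and 0.0523 with an estimated correlation). NMI was at -1.18 ± 0.05, JAK1 at -0.60 ± 0.03 and the receptor gene IFNGR1, on chromosome 6, at -0.80 ± 0.05 (-0.25 with the median of its neighbours subtracted).

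MHC class I genes had 15 of 21 lowered and 2 raised without IFNγ, and 16 and 2 adjusted over the list alone (adjusted p = 3.12e-04, 0.0611 with an estimated correlation and 0.107 with neighbour medians subtracted), among them ERAP2 (-1.75 ± 0.06), TAPBP (-1.11 ± 0.05), NLRC5 (-1.48 ± 0.10) and CALR (-0.28 ± 0.02). Of these 21 genes, 10 lie on chromosome 6, whose genes were lower as a whole, and of the 11 on other chromosomes 9 were lowered. Checkpoint genes had 11 of 17 lowered and 2 raised, and 12 and 2 adjusted over the list alone (adjusted p = 0.0187, and 0.0656 with an estimated correlation). NT5E was at -1.63 ± 0.12, CD276 at 0.51 ± 0.04 and WARS at 0.43 ± 0.02. Cell death genes had 12 of 23 lowered and 2 raised, and 12 and 2 adjusted over the list alone (adjusted p = 0.0197, 0.0602 with an estimated correlation and 0.194 with neighbour medians subtracted). APOL6 was at -3.30 ± 0.08, RIPK1, on chromosome 6, at -0.81 ± 0.05 (-0.27 with the median of its neighbours subtracted), TNFSF10 at -2.13 ± 0.14 and TNFRSF10B at 0.51 ± 0.03. Guanylate-binding protein genes had 3 of 7 lowered and 1 raised, and 3 and 1 adjusted over the list alone (adjusted p = 0.0265, and 0.216 with an estimated correlation). GBP2 was at -2.49 ± 0.04, GBP5 at -1.30 ± 0.04, GBP3 at 0.36 ± 0.06 and GBP1 lower by a ratio of 531 (95% exact interval 181 to 2579). The median of this list was 0.00 and its mean -1.76 as fitted, and its median was -1.90 over the 4 members left when the 3 at 0 in both lines were left out.

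Metabolic and matrix genes differed as well. Hypoxia and glycolysis genes had 18 of 22 raised and 0 lowered, and 18 and 0 adjusted over the list alone (adjusted p = 1.33e-08, and 0.0676 with an estimated correlation), CA9, a carbonic anhydrase, by 3.09 ± 0.10, ENO2 by 1.21 ± 0.05, NDRG1 by 1.56 ± 0.07 and the glucose transporter SLC2A1 by 0.60 ± 0.03. Cholesterol synthesis genes had 13 of 20 lowered and 2 raised, and 13 and 2 adjusted over the list alone (adjusted p = 2.29e-04). SQLE was at -0.95 ± 0.03, HMGCS1 at -1.86 ± 0.08 and MSMO1 at -1.19 ± 0.05. Mesenchymal and matrix genes had 16 of 29 lowered and 10 raised, and 16 and 10 adjusted over the list alone (adjusted p = 0.0250, and 0.221 with an estimated correlation). TGFBI was at -1.59 ± 0.03, FN1 at -2.24 ± 0.05, SPARC at -1.03 ± 0.02 and COL5A2 at -6.01 ± 0.16. Replication histone genes had 8 of 15 lowered and 8 adjusted over the list alone (adjusted p = 0.00188, and 0.0932 without chromosomes 6 and 14). HIST1H2BK was at -1.89 ± 0.04, HIST1H1C at -2.45 ± 0.07, HIST1H2AC at -2.38 ± 0.10 and HIST1H2BC at -2.28 ± 0.24, and 12 of the 15 lie on chromosome 6.

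Endothelial and epithelial markers had 6 of 7 tested members raised in shINCA1 cells, and 6 adjusted over the list alone (adjusted p = 0.0150, and 0.0611 with an estimated correlation). KRT18 rose from 92.0 to 247 CPM (1.43 ± 0.04), CLDN4 by 1.84 ± 0.28, KRT8 by 0.83 ± 0.15 and VWF by 0.92 ± 0.23, while PECAM1, EPCAM and CDH1 had at most 12 counts in any library. Of 14 immune cell markers 3 were tested, 1 raised and 1 lowered, and 1 and 1 adjusted over the list alone (adjusted p = 0.979), and PTPRC had at most 3 counts in any library. Other lists held many single changes without a list call. Neural, glial and stem genes had 9 of 19 lowered and 7 raised, and 9 and 7 adjusted over the list alone (adjusted p = 0.325). CD24 was at 2.97 ± 0.06, PDGFRA at -2.62 ± 0.07, NES, which encodes nestin, at -2.03 ± 0.06 and SOX4 at -1.33 ± 0.04. Proliferation genes had 12 of 28 lowered and 6 raised, and 12 and 6 adjusted over the list alone (adjusted p = 0.156). MCM3 was at -0.55 ± 0.02, but its neighbours on chromosome 6 had a median of -0.54, and with this subtracted it was at -0.01 and no longer called (adjusted p = 0.686). CCNA2 was at -0.70 ± 0.03, MKI67 at -0.69 ± 0.05 and CDK1 at -0.61 ± 0.04.

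Chemokine and cytokine genes had 4 of 15 raised and 2 lowered, and 4 and 2 adjusted over the list alone (adjusted p = 0.655). CXCL16 was at 1.60 ± 0.06, CXCL8 at 2.45 ± 0.16, CSF1 at -1.09 ± 0.08 and IL7 at 2.12 ± 0.23. MHC class II genes had 4 of 14 lowered and 3 raised, and 4 and 3 adjusted over the list alone (adjusted p = 0.699). IFI30 was at 0.54 ± 0.04, RFX5 at -0.45 ± 0.05, RFXAP at -0.65 ± 0.08 and CTSS at least 6.30-fold lower. All 5 genes of the HNRNP H and F family passed, 2 raised and 3 lowered, as they did adjusted over the list alone (adjusted p = 0.890). HNRNPF was at 0.48 ± 0.02, HNRNPH2 at -0.50 ± 0.03 and GRSF1 at 0.16 ± 0.03, the last of which did not hold its sign when the median of neighbouring genes was subtracted (-0.06, adjusted p = 0.076). WARS did not either (-0.05, adjusted p = 0.0711). Median, mean and test differed in sign for the guanylate-binding protein list and for the chemokine, chromosome 9 and immune cell lists, the last 3 of them not called.

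Neighbouring genes differed together between the lines. Over 644 expressed genes of chromosome 6 the median log2 difference without IFNγ was -0.60 and 83.5% were lowered, and over 420 genes of chromosome 14 it was 0.44 and 67.1% were raised. In 500 windows of 25 neighbouring expressed genes, 53 window medians lay beyond 0.4 in either direction, where 1000 shuffles of gene order gave at most 2. All 25 windows of chromosome 6 and 9 of 16 on chromosome 14 were among them. The SD of the window medians was 0.2317, against at most 0.0985 in shuffles (permutation p = 0.001, the smallest these can give). No window passed 0.4 in either IFNγ response, where window medians spread far less. Their SD still exceeded every shuffle (0.0404 against 0.0361 in shCTRL and 0.0298 against 0.0284 in shINCA1 cells, permutation p = 0.001 each). Other list members named for this comparison that moved by more than 1.5 times with neighbour medians subtracted were NT5E (-0.95), TAPBP (-0.50), SOX4 (-0.62), HIST1H2BK (-1.23), MSMO1 (-0.77), MKI67 (-0.23), IRF1 (-0.23) and CD276 (0.17). Those named with IFNγ were TAP1 (-0.79), TAP2 (-0.34), TAPBP (-0.45), HLA-E (-0.36), RIPK1 (-0.41), WARS (-0.91), HNRNPH1 (-0.12) and GRSF1 (-0.07).

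**Figure D2:**
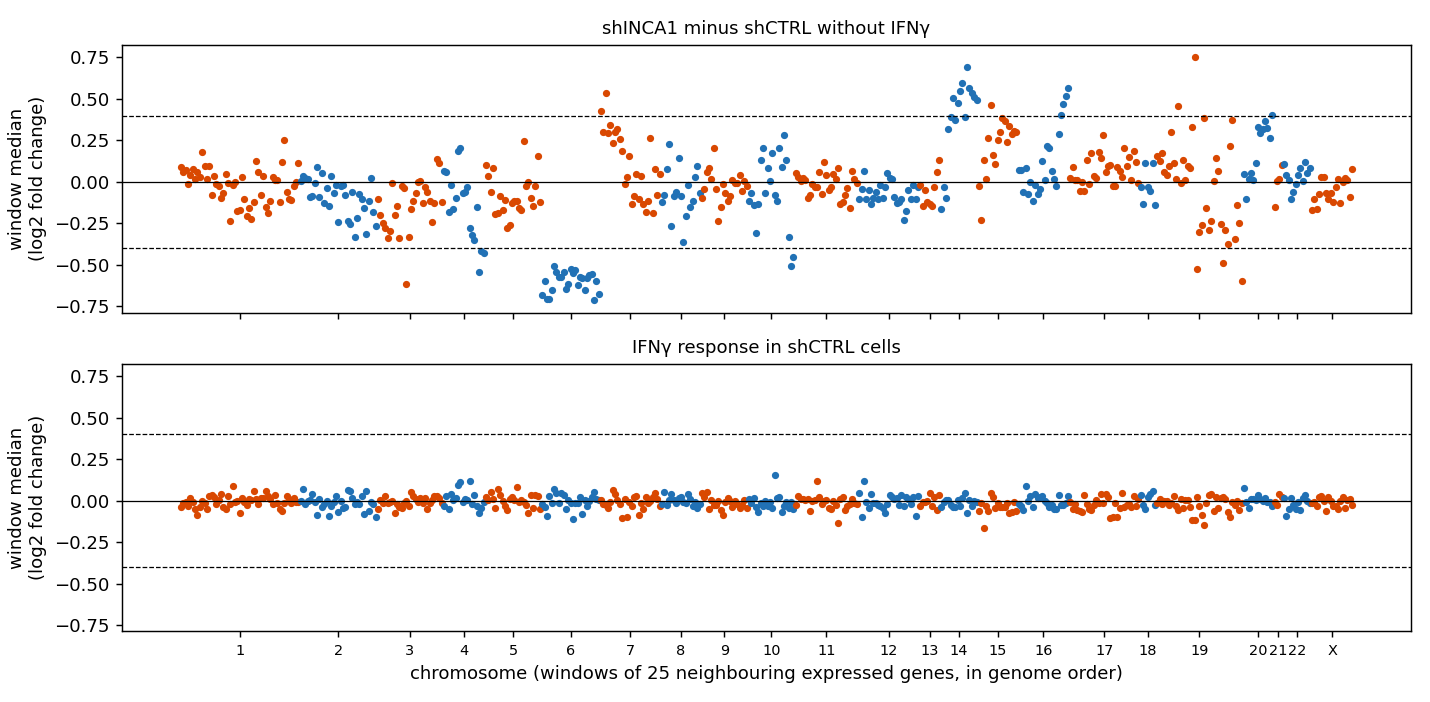
Median log2 fold change of 500 windows of 25 neighbouring expressed genes, in genome order, with chromosomes in alternating colours and dashed lines at 0.4 in both directions. In the upper panel (shINCA1 minus shCTRL without IFNγ) all 25 windows of chromosome 6 lie below the lower line and 9 of 16 of chromosome 14 above the upper line, and in the lower panel (IFNγ response in shCTRL cells) no window reaches either line.

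In edgeR's quasi-likelihood test 4314 genes were higher and 4656 lower in shINCA1 than in shCTRL cells without IFNγ, 56.9% of those tested, and 1015 and 961 of them differed at least 2-fold. Groups did not overlap for 62.8% of genes, against 10% by chance, and the design cannot separate the hairpin from other differences between the lines.

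With IFNγ present, the same comparison of the lines was asked again. CD274 differed by -1.25 ± 0.10 (SE), JAK2 by -1.46 ± 0.08, IDO1 by -2.21 ± 0.06, IRF1 by -0.58 ± 0.05 and PDCD1LG2 by -0.95 ± 0.15, all lower in shINCA1 cells with an adjusted p of at most 1.80e-04. IDO1 stood at 101 ± 5.92 CPM (SD, n = 3) in shCTRL and 21.8 ± 0.79 CPM in shINCA1 cells. HNRNPH1 differed by -0.07 ± 0.02 (adjusted p = 0.00502). COL17A1 (6.24 ± 0.05), PDE3B (5.67 ± 0.45), WNT7B (5.57 ± 0.20) and NTRK3 (5.18 ± 0.72) were higher in shINCA1 cells, and GJB5, GPC3 and CDH23 by ratios of 150 (95% exact interval 68.7 to 410), 139 (47.1 to 676) and 78.2 (35.6 to 214). COL1A2 was at least 792-fold lower, HAPLN1 401-fold, LRRTM2 288-fold, ZNF518B 144-fold, PICK1 143-fold, HSD17B7 134-fold and C4A, whose reads can be shared with its paralog C4B, 138-fold, each as a lower bound against 0.

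Nearly all interferon lists were lower in treated shINCA1 than in treated shCTRL cells. Antiviral genes had 31 of 36 lowered and 2 raised, and 31 and 2 adjusted over the list alone (camera adjusted p = 9.02e-11). IFITM1 was at -3.36 ± 0.15, IFIT3 at -1.91 ± 0.09, SAMD9L at -3.46 ± 0.17 and IFITM2 at 0.87 ± 0.05. JAK-STAT genes had 16 of 18 lowered and 1 raised, and 17 and 1 adjusted over the list alone (adjusted p = 1.49e-06). JAK1 was at -0.67 ± 0.04 and NMI at -0.73 ± 0.05. MHC class I genes had 19 of 21 lowered and 19 adjusted over the list alone (adjusted p = 1.38e-08). TAP1 was at -1.39 ± 0.03, TAPBP at -1.06 ± 0.05, HLA-E at -0.89 ± 0.04 and TAP2 at -0.96 ± 0.05, with 10 of the 11 members outside chromosome 6 lowered. MHC class II genes had 11 of 14 lowered and 11 adjusted over the list alone (adjusted p = 0.00177). CIITA was at -1.14 ± 0.07, CTSS at -4.05 ± 0.26, IFI30 at -0.60 ± 0.04 and RFX5 at -0.43 ± 0.05, and 7 of the 14 lie on chromosome 6. Checkpoint genes had 14 of 17 lowered and 1 raised, and 14 and 1 adjusted over the list alone (adjusted p = 7.36e-05). WARS was at -0.43 ± 0.02.

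Guanylate-binding protein genes had 4 of 7 lowered and 1 raised with IFNγ, and 5 and 1 adjusted over the list alone (adjusted p = 1.91e-04, and 0.0611 with an estimated correlation). GBP2 was at -1.94 ± 0.03, GBP5 at -1.34 ± 0.03, GBP1 at -2.77 ± 0.09 and GBP4 at -2.49 ± 0.06. Cell death genes had 17 of 23 lowered and 3 raised, and 18 and 4 adjusted over the list alone (adjusted p = 5.29e-05). APOL1 was at -3.26 ± 0.07, APOL3 at -4.32 ± 0.17, APOL6 at -1.02 ± 0.05 and RIPK1 at -0.95 ± 0.05. Chemokine and cytokine genes had 8 of 15 lowered and 3 raised, and 8 and 3 adjusted over the list alone, without a list call (adjusted p = 0.0787). Within it CXCL9 differed by -7.29 ± 0.17 and CXCL10 by -5.32 ± 0.13, CXCL16 by 1.17 ± 0.06 and CXCL8 by 3.11 ± 0.17.

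Lists unrelated to interferon were called with IFNγ too. Hypoxia and glycolysis genes had 18 of 22 raised and 1 lowered, and 18 and 1 adjusted over the list alone (adjusted p = 2.69e-07, and 0.0860 with an estimated correlation). CA9 was at 3.18 ± 0.10. Cholesterol synthesis genes had 13 of 20 lowered and 2 raised, and 13 and 2 adjusted over the list alone (adjusted p = 4.81e-04). HMGCS1 was at -1.80 ± 0.08. Replication histone genes had 8 of 15 lowered and 8 adjusted over the list alone (adjusted p = 0.00552, 0.0554 with neighbour medians subtracted and 0.198 without chromosomes 6 and 14). HIST1H1C was at -2.38 ± 0.07. Mesenchymal genes had 18 of 29 lowered and 9 raised, and 19 and 9 adjusted over the list alone (adjusted p = 0.0250, and 0.208 with an estimated correlation). FN1 was at -2.41 ± 0.05, ANKRD1 at 1.84 ± 0.03 and THBS1 at 1.01 ± 0.02. Endothelial and epithelial markers had 5 of 7 raised and 5 adjusted over the list alone (adjusted p = 0.0197, and 0.0692 with an estimated correlation). KRT18 was at 1.57 ± 0.04 and KDR at 0.72 ± 0.08.

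The unfolded protein and stress list had 10 of 20 lowered and 2 raised, and 10 and 2 adjusted over the list alone (adjusted p = 0.0396, and 0.276 with an estimated correlation), and lost its call without shCTRL IFNγ library 2 (adjusted p = 0.0536). The p53 list had 7 of 14 raised and 5 lowered, and 7 and 5 adjusted over the list alone (adjusted p = 0.488). The NF-κB list had 5 of 19 raised and 9 lowered, and 5 and 10 adjusted over the list alone (adjusted p = 0.449). The chromosome 9 list had 5 raised and 5 lowered of 17, also adjusted over the list alone (adjusted p = 0.90). GRSF1 of the HNRNP H and F family was at 0.16 ± 0.03, and at -0.07 (adjusted p = 0.0564) with the median of neighbouring genes subtracted. Median, mean and test differed in sign for the chromosome 9 list and for the neural list, neither of them called.

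**Figure D3:**
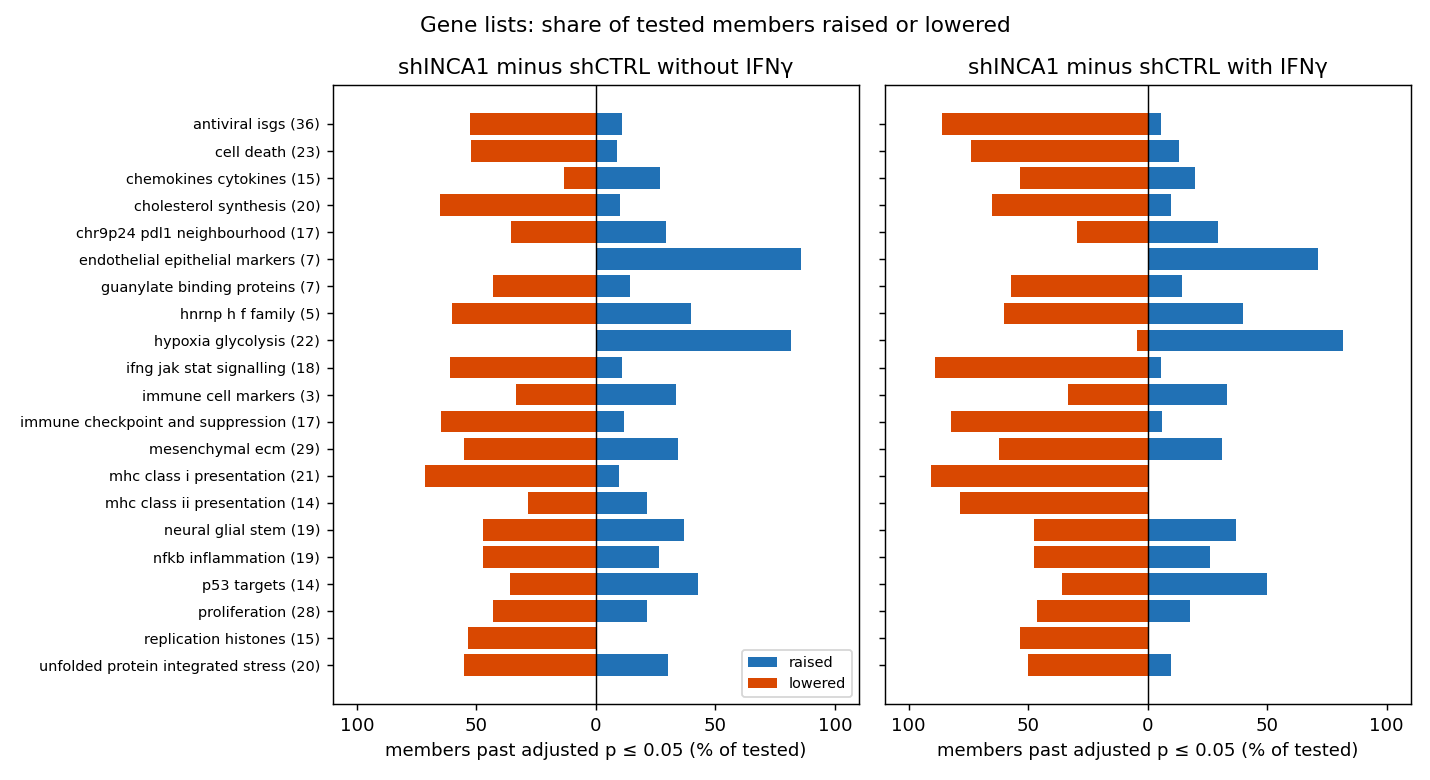
Share of tested members of 21 gene lists (number tested in brackets) that were higher (blue) or lower (orange) in shINCA1 than in shCTRL cells at an adjusted p of 0.05, in percent, without IFNγ (left) and with IFNγ (right). Lowered members of the MHC class I list number 15 of 21 on the left and 19 of 21 on the right.

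With IFNγ, edgeR's quasi-likelihood test called 4529 genes higher and 4762 lower in shINCA1 cells, 58.9% of those tested and 1097 and 973 of them at least 2-fold, and 66.5% of genes did not overlap, against 10% by chance. The calls without and with IFNγ shared 3713 raised genes where independent lists would share 1239 and 4037 lowered genes where 1406 would be shared. The groups compared have no library in common, but the fit and its estimate of the spread are shared, so these calls are not fully independent.

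Whether the IFNγ response itself differed between the lines was tested as a difference of responses. A response is a log2 ratio to the line's own untreated level, so it can be larger where the treated level is lower. The difference is shINCA1 minus shCTRL, so a smaller fall counts as positive. In counts of list members below, larger and smaller give its sign. The response of JAK2 was smaller in shINCA1 cells by a log2 difference of -1.04 ± 0.11 (SE, adjusted p = 5.27e-04). That of SOCS1, a feedback inhibitor of JAK kinases, was smaller by -2.05 ± 0.32 (adjusted p = 0.00672) and that of TAP1 by -1.11 ± 0.04 (adjusted p = 1.96e-07). HAPLN3 rose from 1.64 to 19.0 CPM in shCTRL cells and went from 0.551 to 0.360 CPM in shINCA1 cells (-4.15 ± 0.24, adjusted p = 2.56e-06). ADAP1 (-2.72 ± 0.25) and MDGA1 (-1.64 ± 0.20) had smaller responses, while APOL6 (2.28 ± 0.10, adjusted p = 2.08e-07) and PARP10 (1.88 ± 0.23) had larger ones. FILIP1L (1.47 ± 0.21) and ADGRE2 (1.72 ± 0.14) differed in the same direction, falling from 9.07 to 2.54 and from 3.84 to 1.27 CPM in shCTRL cells. In shINCA1 cells they stood at 5.96 and 4.62 and at 8.50 and 9.37 CPM without a call. The responses of CD274 (0.37 ± 0.16, adjusted p = 0.407), PDCD1LG2 (0.49 ± 0.26, adjusted p = 0.528) and HNRNPH1 (0.05 ± 0.03, adjusted p = 0.561) were not past the threshold. IRF1 was not either (-0.21 ± 0.07, adjusted p = 0.245), but passed without untreated shINCA1 library 2 (-0.29, adjusted p = 0.0291), and no difference could be estimated for IDO1, which was at 0 in both untreated groups.

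Genes near the floor of 3 counts per library passed too, and for these only levels are given. GBP1 went from 8.61 to 984 CPM in shCTRL and from 0.0148 to 144 CPM in shINCA1 cells (adjusted p = 2.10e-06), OAS1 from 0.360 to 2.93 and from 0 to 0.736 CPM (adjusted p = 0.0144), both larger responses in shINCA1. CORO7-PAM16 went from 1.97 to 1.55 and from 2.19 to 0 CPM (adjusted p = 2.34e-04), a negative difference. BATF2 went from 0.0276 to 9.31 and from 0.254 to 4.48 CPM (adjusted p = 0.0158), a smaller response whose call was lost without untreated shINCA1 library 3 (adjusted p = 0.0582). TRIM22 went from 2.11 to 50.1 and from 0.0396 to 6.83 CPM (adjusted p = 0.0416), a larger response whose call was lost without any 1 of the libraries except untreated shINCA1 library 3 (adjusted p 0.0596 to 0.110). Above the floor, the smaller response of IFI44L (-2.15 ± 0.41, adjusted p = 0.0226) was lost without untreated library 2 or IFNγ library 1 or 2 of shCTRL, or untreated library 2 or 3 or IFNγ library 1 or 2 of shINCA1 (adjusted p 0.0538 to 0.0870). HAS2 (1.25 ± 0.24, adjusted p = 0.0215) was lost without untreated library 1 or 3 or IFNγ library 1 of shCTRL, or untreated library 1 or 3 or IFNγ library 3 of shINCA1 (adjusted p 0.0508 to 0.0637).

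Within the MHC class I list 5 of 21 responses were smaller and 3 larger in shINCA1 cells, and 9 and 3 adjusted over the list alone (camera adjusted p = 5.91e-05). TAP1, HLA-B (-1.14 ± 0.12) and HLA-E (-0.57 ± 0.06) were smaller and ERAP2 (0.94 ± 0.07) was larger. The median of this list was -0.08 and its mean 0.06 as fitted, and its median was -0.11 with the 1 member at 0 in a group left out. The 5 smaller responses all lie on chromosome 6 and the 3 larger ones on other chromosomes, and without chromosomes 6 and 14 the list pointed up (adjusted p = 0.0144). Most members did not share this direction: of the 11 outside chromosome 6, 7 had a negative difference, with a median of -0.02. The 3 larger ones, TAPBPL, ERAP2 and NLRC5, started lower in shINCA1 cells, which by itself makes a fold larger. MHC class II genes had 1 of 14 smaller, and 3 smaller and 2 larger adjusted over the list alone (adjusted p = 7.10e-04, and 0.187 without chromosomes 6 and 14), IFI30 by -1.13 ± 0.06. JAK-STAT genes had 3 of 18 smaller and 1 larger, and 5 and 2 adjusted over the list alone (adjusted p = 7.34e-04), JAK2, SOCS1 and BATF2 smaller and NMI larger (0.45 ± 0.07). Cell death genes had 5 of 23 smaller and 2 larger, and 7 and 4 adjusted over the list alone (adjusted p = 0.00612). APOL2 was at -0.70 ± 0.07 and the death receptor gene FAS at -0.87 ± 0.12.

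Antiviral genes had 9 of 36 responses smaller and 5 larger, and 14 and 7 adjusted over the list alone (adjusted p = 0.0184, and 0.0973 with an estimated correlation), a call lost without untreated shINCA1 library 2 (adjusted p = 0.152). IFIT5 was at -0.46 ± 0.04, DTX3L at 0.79 ± 0.06 and PARP9 at 1.02 ± 0.10. Guanylate-binding protein genes had 2 of 7 larger and 2 adjusted over the list alone (adjusted p = 0.0105, and 0.175 with an estimated correlation), GBP1 and GBP2 (0.55 ± 0.05). Their median was -0.20 and their mean 0.30 as fitted, and the median was 0.25 over the 4 members left when the 3 at 0 in a group, all negative as fitted, were left out. The unfolded protein and stress list pointed down without any of 20 genes past the threshold, and with 3 smaller and 1 larger adjusted over the list alone (adjusted p = 0.00317, and 0.123 with an estimated correlation). Neural, glial and stem genes pointed up (adjusted p = 0.00444, and 0.0825 without chromosomes 6 and 14). The difference was positive for 1 of 19, SOX4 of chromosome 6 (0.42 ± 0.05), which fell less in shINCA1 cells. Adjusted over the list alone, 3 were positive and 1 negative. Lists not called included the checkpoint genes (3 of 17 smaller, 3 smaller and 1 larger adjusted over the list alone, adjusted p = 0.151). WARS was at -0.86 ± 0.03, and the chemokines (2 of 15 smaller, 3 smaller and 1 larger adjusted over the list alone, adjusted p = 0.133). CX3CL1 was at -0.67 ± 0.10. The mesenchymal list (3 of 29 larger and 2 smaller, and 6 and 2 adjusted over the list alone, adjusted p = 0.0750) passed without untreated shINCA1 library 2 (0.0365) or shINCA1 IFNγ library 3 (0.0267). Median, mean and test differed in sign for the MHC class I, guanylate-binding protein and cell death lists and for the cholesterol, chromosome 9, mesenchymal and p53 lists, the last 4 of them not called.

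Of the genes tested, 97 had a positive and 173 a negative difference of responses in edgeR's quasi-likelihood test, 13 and 22 of them at least 2-fold. An unadjusted p under 0.05 was found for 1800. Genes that fell with IFNγ are among the calls, so a positive difference can be a smaller fall. Leaving out untreated library 2, IFNγ library 1 or IFNγ library 2 of shCTRL, or untreated library 3 or IFNγ library 2 of shINCA1, gave 112, 115, 100, 95 and 100 negative differences. Leaving out shINCA1 IFNγ library 3 gave 57 positive ones, and DESeq2 called 178 positive and 332 negative.

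Genes of the average IFNγ response over both lines were followed as a group. CD274 (4.02 ± 0.09), IRF1 (5.85 ± 0.04), PDCD1LG2 (3.70 ± 0.13) and JAK2 (1.42 ± 0.06) rose on average, and HNRNPH1 did not pass (-0.02 ± 0.01, adjusted p = 0.370). GBP4, IDO1, CIITA, CXCL9, CXCL10, CXCL11, GBP1P1 and LGALS17A led the raised genes. BOLA2 changed by -2.66 ± 0.70, CXCR4 by -1.72 ± 0.21, CNR1 by -1.53 ± 0.14, SOSTDC1 by -1.51 ± 0.22 and NDP by -1.42 ± 0.10. CORO7-PAM16, GPC3 and TACR1 were lowered with at least 1 group near the floor, so no fold is given. The average response raised 1782 and lowered 1411 genes (1329 and 2512 with upper-quartile factors), 317 and 43 of them at least 2-fold. Of the 317 genes, 49 had a smaller and 17 a larger response in shINCA1 cells, and 31 were smaller without shINCA1 IFNγ library 2. Above the floor in all groups were 229 of them, with a median difference of responses of -0.26 against 0.01 over all genes, 166 negative and 63 positive (camera p = 3.88e-20, and p = 2.16e-06 with an estimated correlation). In the comparison of lines 205 of the 317 were lower and 29 higher in shINCA1 cells with IFNγ, and 148 and 62 without.

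**Figure D4:**
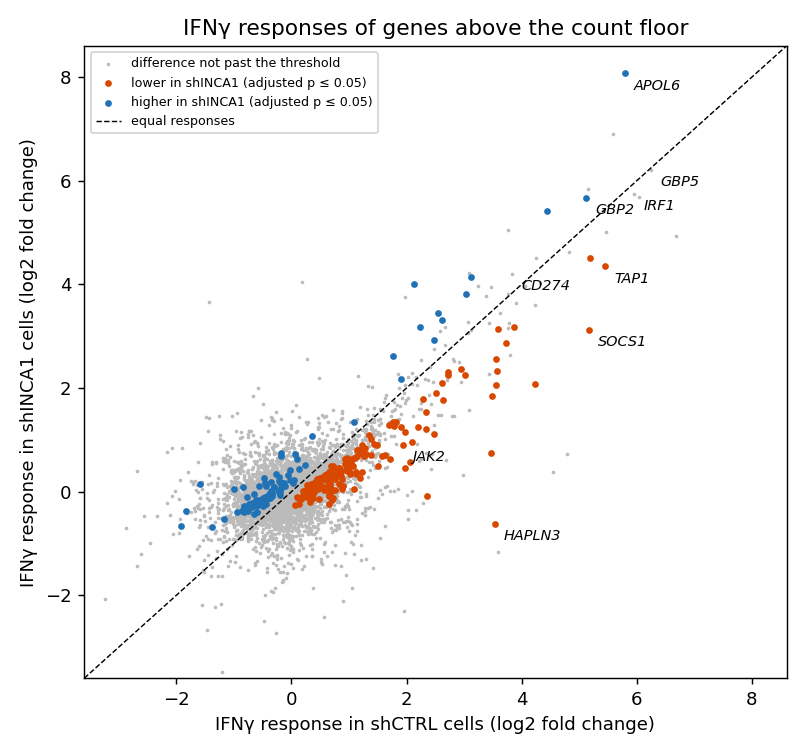
IFNγ response (log2 fold change) of each gene above the count floor in shCTRL (x axis) and shINCA1 cells (y axis), with a dashed line at equal responses. Genes whose responses differed at an adjusted p of 0.05 are in orange (negative difference, shINCA1 minus shCTRL) and blue (positive difference). JAK2, SOCS1, TAP1 and HAPLN3 lie below the line and APOL6 and GBP2 above it, while CD274, IRF1 and GBP5 were not past the threshold.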

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

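Tests of single genes and lists in the difference of IFNγ responses were chosen before the data were examined. The test of GC content and gene length was chosen after chromosome 6 had stood out, but before its own result was seen. The tests of all other explanations and all counts of other splits of the samples were chosen after the result was seen.

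The genes of this paragraph stood out because the difference of IFNγ responses between the lines passed the threshold itself, with a smaller response in shINCA1 cells. Signalling genes among them were JAK2 (log2 difference -1.04, adjusted p = 5.27e-04) and SOCS1 (-2.05, adjusted p = 0.00672). Antigen presentation genes were TAP1 (-1.11, adjusted p = 1.96e-07), HLA-B (-1.14, adjusted p = 3.63e-04), HLA-E (-0.57, adjusted p = 2.80e-04) and IFI30 (-1.13, adjusted p = 1.60e-06). Others were WARS (-0.86, adjusted p = 1.38e-07), HAPLN3 (-4.15, adjusted p = 2.56e-06), ADAP1 (-2.72, adjusted p = 1.71e-04), MDGA1 (-1.64, adjusted p = 0.00131), IFIT5 (-0.46, adjusted p = 2.03e-04), APOL2 (-0.70, adjusted p = 2.21e-04), FAS (-0.87, adjusted p = 0.0027) and CX3CL1 (-0.67, adjusted p = 0.00461). CXCL16 (-0.42, adjusted p = 0.0206) lost its call without IFNγ library 2 or 3 of shCTRL, IFNγ library 1 or 2 of shINCA1 or untreated shINCA1 library 3 (adjusted p 0.0537 to 0.0709). IFI44L (-2.15, adjusted p = 0.0226) lost it without untreated library 2 or IFNγ library 1 or 2 of shCTRL, or untreated library 2 or 3 or IFNγ library 1 or 2 of shINCA1 (adjusted p 0.0538 to 0.0870). Near the floor were BATF2 (adjusted p = 0.0158, and 0.0582 without untreated shINCA1 library 3) and, as a negative difference without a rise in either line, CORO7-PAM16 (adjusted p = 2.34e-04). CXCL16, IFI30, WARS, HLA-B and BATF2 stood higher in untreated shINCA1 than in untreated shCTRL cells, which by itself makes a fold smaller. CXCL16 was still higher in shINCA1 cells with IFNγ. JAK2, TAP1, HLA-E and HAPLN3 stood lower in untreated shINCA1 cells.

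A larger rise in shINCA1 cells, as a fold of the line's own untreated level, was found by the same test for APOL6 (2.28, adjusted p = 2.08e-07), PARP10 (1.88, adjusted p = 0.00132), PARP9 (1.02, adjusted p = 2.70e-04), ERAP2 (0.94, adjusted p = 4.79e-05), DTX3L (0.79, adjusted p = 3.55e-05), GBP2 (0.55, adjusted p = 2.27e-04) and NMI (0.45, adjusted p = 0.00477). APOL6, ERAP2, GBP2, NMI, DTX3L and PARP9 started lower in shINCA1 cells and were still lower there with IFNγ. Near the floor were GBP1 (adjusted p = 2.10e-06), OAS1 (adjusted p = 0.0144) and TRIM22 (adjusted p = 0.0416), whose call was lost without any 1 library except untreated shINCA1 library 3 (adjusted p 0.0596 to 0.110). Positive differences of genes that fell in shCTRL cells were those of ADGRE2 (1.72, adjusted p = 7.22e-05), FILIP1L (1.47, adjusted p = 0.00389), SOX4 (0.42, adjusted p = 0.00169) and HAS2 (1.25, adjusted p = 0.0215). HAS2 lost its call without untreated library 1 or 3 or IFNγ library 1 of shCTRL, or untreated library 1 or 3 or IFNγ library 3 of shINCA1 (adjusted p 0.0508 to 0.0637).

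Gene lists stood out by the same difference. Negative differences, shINCA1 minus shCTRL, were called for MHC class I (adjusted p = 5.91e-05), MHC class II (adjusted p = 7.10e-04), JAK-STAT (adjusted p = 7.34e-04), unfolded protein and stress (adjusted p = 0.00317), cell death (adjusted p = 0.00612) and antiviral genes (adjusted p = 0.0184, and 0.152 without untreated shINCA1 library 2). Positive differences were called for neural, glial and stem genes (adjusted p = 0.00444) and for guanylate-binding proteins (adjusted p = 0.0105). The sign of a call and that of the median or mean of the members were not the same for cell death (median -0.14, mean 0.12), MHC class I (-0.08 and 0.06) and guanylate-binding proteins (-0.20 and 0.30). Without chromosomes 6 and 14 the calls of the MHC class II and neural lists were lost (adjusted p 0.187 and 0.0825) and MHC class I pointed up (adjusted p = 0.0144). Of the 11 MHC class I members outside chromosome 6, though, 7 had a negative difference, with a median of -0.02. The calls of the stress, antiviral and guanylate-binding lists were lost with an estimated correlation (adjusted p 0.123, 0.0973 and 0.175).

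Runs of neighbouring genes differed between the lines, with a median of -0.60 over 644 genes of chromosome 6 and 0.44 over 420 genes of chromosome 14. GC content or gene length bias is argued against, since chromosome 6 genes had a median difference of -0.588 (95% bootstrap interval -0.64 to -0.558) to genes of other chromosomes matched on both. A difference in chromosome copy number between the lines is a candidate explanation, as a hypothesis: window medians with and without IFNγ had an r of 0.969, and 53 windows passed 0.4 where shuffled orders gave at most 2 and the IFNγ responses none. The IFNγ responses say little here, as their window medians spread far less (SD 0.0404 in shCTRL and 0.0298 in shINCA1 cells, against 0.2317 between the lines without IFNγ). DNA was not analysed here. Loss of the targeted RNA stays open beside it, since the labels tell apart 1 line per hairpin, and the hairpin and the line cannot be told apart.

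MHC class I genes were lower in shINCA1 than in shCTRL cells (list adjusted p = 3.12e-04 without IFNγ, but 0.0611 with an estimated correlation and 0.107 with neighbour medians subtracted). That subtraction moved the list median from -0.289 to -0.231, with 12 members lowered and 8 raised, against 15 and 2 before. Among the 10 members on chromosome 6 without IFNγ, a lower dosage of that chromosome may be enough for the lowered ones except TAPBP. TAPBP was at -1.11, further down than the chromosome's median of -0.60. As a set the 10 were not detectably lower than the chromosome's other genes (median -0.31 against -0.60, camera p = 0.524 with an estimated correlation). That test includes raised members, so it does not speak for the lowered ones alone. HLA-B (0.29) and HLA-C (0.55) were raised, which a lower dosage alone would not give, though HLA genes share reads. In the difference of IFNγ responses a lower dosage of the members' own copies is argued against. There the 10 members lay below the other genes of chromosome 6 (median -0.45 against 0.01, camera p = 0.00102 with an estimated correlation). Effects of that chromosome's dosage through other genes, such as IFNGR1, were not tested. Reads shared between HLA genes stay open for the difference of responses: the 5 members on chromosome 6 that are not HLA genes had a median of -0.397 with TAP1, TAP2 and PSMB8 called, but TAPBP was at 0.05. Of the 11 members on other chromosomes 9 were lowered without IFNγ and 10 with it, which neither shared HLA reads nor a lower dosage of the members' own chromosome 6 copies covers.

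Genes raised in the average response had smaller responses in shINCA1 cells, with a median difference of -0.26 over 229 genes above the floor. Counts near the floor are argued against as the cause, since these genes are all above it (camera p = 2.16e-06 with an estimated correlation). The folds of the line's own untreated level were not all smaller, as 13 genes above the floor were called with a larger response. Among them, APOL6 and GBP2 differed between the lines by -3.30 and -2.49 without IFNγ and by -1.02 and -1.94 with it. A lower untreated level by itself makes a fold larger. These calls therefore cannot tell whether induction was weaker by one factor for every gene, and this stays open. Loss of the targeted RNA could be the cause and stays open as a hypothesis, since the labels tell apart 1 line per hairpin and any other difference between the lines would act in the same comparison.

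Other splits of the same samples were counted for each comparison. In the IFNγ response of shCTRL cells 1 of 10 splits, the real one, gave 2716 genes and the highest other 2, and in shINCA1 cells the values were 1432 and 3. Without IFNγ the lines gave 8970 genes and the highest other split 2, and with IFNγ 9291 and 2. Those splits are too few for a share under 0.05. For the difference of responses 2 of 50 splits, the real one included, gave at least 270 genes. The highest other split gave 3670 and the next 20. That split exchanged 2 samples per group between the lines in untreated cells and 0 with IFNγ, so it carries the difference between the lines into the tested difference and points to this structure of the samples. For the average response 1 of 50 splits, the real one with 3193 genes, was as large, and the highest other gave 1050. Exchanged samples carry differences between lines or treatments into the spread within groups, which by design lowers the counts of other splits, so whether chance can be excluded is left open.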

How the results depend on the processing

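The settings that subtract neighbour medians, leave out chromosomes 6 and 14 or leave out genes near the floor were chosen after seeing the data, and the others before.

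Among single genes and lists, 8538 results under planned settings stayed on their side of the threshold, and those called kept their direction. A change of sign without a call was not counted. Out of a call fell 277 and 31 came into one. Of the 277, 127 were genes under a minimum fold of 2, which the stricter hypothesis itself explains. Alternatives planned for FPKM values only were not run, since the table holds counts. DESeq2 size factors and no low-count filter moved no count by more than 1.5 times.

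Upper-quartile factors gave 1970 lowered genes in the IFNγ response of shCTRL cells (1184 with TMM), 733 in shINCA1 cells (465) and 2512 in the average response (1411), and the cause was not tested. An adjusted p of 0.01, stricter by construction, left 605 and 195 lowered genes in the shCTRL and shINCA1 responses, 42 positive and 71 negative differences of responses and 792 lowered genes on average. A minimum fold of 2 left 223 raised and 10 lowered genes in shCTRL, 153 and 1 in shINCA1, 529 and 583 between the lines without IFNγ, 571 and 585 with it, 3 and 3 in the difference of responses and 204 and 6 on average. The DESeq2 Wald test called 733 lowered genes in the shINCA1 response and 178 positive and 332 negative differences of responses, and the cause was not tested.

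A filter of 5 CPM in 3 samples, which leaves fewer and more abundant genes, gave an r of 0.85, a rho of 0.566 and a slope of 0.758 between the responses of the lines (0.615, 0.434 and 0.536 without it). With the replicate block r was 0.59, 5 results of named genes and 1 of a list lost their call and 1 list came into one, and the cause was not tested. An estimated correlation called 3 lists between the lines without IFNγ (11 at 0.01), 8 with IFNγ (13) and 5 in the difference of responses (8), and fry, which does not compare a list with other genes, called 17 lists in the shCTRL response (11) and 17 between the lines without IFNγ (11).

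With the neighbour medians subtracted, WARS turned to -0.052 (adjusted p = 0.0711) and GRSF1 to -0.063 (adjusted p = 0.076) without IFNγ, and GRSF1 to -0.0676 with it (adjusted p = 0.0564), none of them called. MCM3 lost its call without IFNγ (-0.0127, adjusted p = 0.686) and with it (-0.0254, adjusted p = 0.393), as did the MHC class I and cell death lists without IFNγ (adjusted p = 0.107 and 0.194) and the histone list with it (adjusted p = 0.0554), while the chemokine list came into a call with IFNγ (adjusted p = 0.0287). By construction this takes away what neighbours share, and WARS lies in a raised window of chromosome 14. Without chromosomes 6 and 14 the MHC class I list pointed up in the difference of responses (adjusted p = 0.0144), since all of its called smaller responses lie on chromosome 6. Its members outside chromosome 6 did not mostly share this direction, as 7 of 11 had a negative difference. Calls were lost for the histone list without and with IFNγ (adjusted p = 0.0932 and 0.198, with 12 of its 15 genes left out), cell death without it (0.0502), the neural and p53 lists in the shINCA1 response (0.187 and 0.0755) and MHC class II and neural genes in the difference of responses (0.187 and 0.0825).

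Leaving out 1 library at a time gave 281 to 481 lowered genes in the shINCA1 response, 57 to 92 positive and 95 to 154 negative differences of responses, 31 to 48 negative ones among genes raised on average, and r of 0.578 to 0.60, rho of 0.398 to 0.429 and slope of 0.481 to 0.534 between the lines. The 281 came without untreated shINCA1 library 3, the 57 without IFNγ library 3 of shINCA1 and the 31 without its IFNγ library 2. Negative differences numbered 112 without untreated shCTRL library 2, 115 and 100 without IFNγ library 1 and 2 of shCTRL, 95 without untreated shINCA1 library 3 and 100 without IFNγ library 2 of shINCA1. The remaining 2 libraries of a group are then assumed to vary like the other groups. Depth limits genes near the floor of 3 counts, about 1 fragment, for which folds are bounds or ratios.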

Other observations

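The tests of genes lowered in the average response with camera and of lists within chromosome 6 were chosen after the result was seen. Some genes were on in 1 line and off in the other, and they were singled out after their values were seen. At 0 in all 6 shINCA1 libraries and at 1 CPM or more in all 6 shCTRL libraries were 26 genes. They include genes of the matrix and cell surface, with COL1A2 at a mean of 43.1 CPM in shCTRL cells, the hyaluronan link protein gene HAPLN1 at 21.5, the heparan sulfate enzyme gene NDST4 at 4.06, the endothelin receptor gene EDNRB at 2.01 and the angiopoietin gene ANGPT2 at 2.14. Others are PDZRN3 (10.5), ZNF518B (8.16), PICK1 (8.07), HSD17B7 (7.18), the synaptic vesicle gene SYNGR1 (5.54), the transcription factor gene SALL3 (5.27), the metallothionein gene MT1E (4.46), VGLL3 (3.18) and AFF2 (2.86). The other way there were 2 genes, KRTAP3-1 (1.77) and EPHA6 (1.59).

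The median log2 difference of the 10 nearest expressed genes without IFNγ was -0.25 around COL1A2, 0.035 around HAPLN1, -0.658 around PDZRN3, -0.894 around VGLL3, -0.477 around HSD17B7, -0.32 around NDST4, -0.289 around ZNF518B, -0.064 around SALL3, 0.017 around SYNGR1, 0.029 around EDNRB, 0.034 around ANGPT2, 0.057 around PICK1, 0.115 around AFF2 and 0.127 around MT1E. Beside chromosomes 6 and 14, windows beyond 0.4 lay on chromosomes 16 (4 raised), 7 (2 raised), 15 and 20 (1 raised each), 4 (3 lowered), 10 (2 lowered), 3 (1 lowered) and 19 (2 raised and 3 lowered), and the median of chromosome 15 was 0.24 and of chromosome 20 was 0.20. For expressed genes, log2 differences between the lines beyond 2 in either direction were set to that limit. The neighbour median then held 13.0% of their variance without IFNγ and 12.96% with it. Across 14993 genes the difference between the lines without and with IFNγ had an r of 0.878, a rho of 0.85 and a slope of 0.894, and genes are not independent replicates.

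Genes lowered in the average IFNγ response went the same way as the raised ones, toward a smaller response. Of 43 genes 25 were above the floor, with a median difference of responses of 0.56, 2 negative and 23 positive (camera p = 2.20e-04 with an estimated correlation). Among all 43, 5 were called with a positive and 1 with a negative difference. Chromosome 6 members of the MHC class II list lay above the other genes of that chromosome without IFNγ (median -0.34 against -0.60, p = 0.0336 with an estimated correlation) and below them in the difference of responses (median -1.37, p = 0.0113), while 12 histone genes there did not differ detectably without IFNγ (p = 0.738). In the difference of responses the only called gene of the class II list was IFI30, which is not on chromosome 6. Of that list's 14 tested members 3 were at 0 in a group, and HLA genes share reads.

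Tested genes at 0 in a library and at 100 counts or more in another of the same group numbered 42, and 23 of them had joined read-through symbols, of which 113 were tested.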
